A study of Bos taurus with 6 samples.

How the data were processed

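RNA of articular cartilage from 2 skeletally mature cattle was hybridised to 6 Affymetrix bovine arrays, 1 for each of 3 zones in each animal. Per the labels' protocols, osteochondral cores from the femoral condyles were cut on a microtome into sections of 50 µm from the joint surface towards the calcified cartilage. The upper 10% of the sections formed the superficial zone (SZ), the middle 40% the middle zone (MZ) and the lower 30% the deep zone (DZ), and about 200 µm was discarded between neighbouring zones. From each zone 5 ng of total RNA was amplified with a whole-transcriptome kit before labelling, per the labels' protocols.

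The values tested were those of the deposited value table, which holds 1 log2 expression value per probeset and array, already normalised between arrays by the authors. The submitters' processing notes name RMA, without a version. The log2 scale was read from the values, whose medians lay between 4.42 and 4.46 on the 6 arrays. A separate deposited matrix whose name carries dCHIP also holds log2 values, and it served as an alternative and as the source of gene symbols. Background method, chip definition, dCHIP settings and software were not given in the sources used here. Array by array, the deviations from the mean of the 6 arrays correlated between both tables with r of 0.766 to 0.846 across probesets, and no array correlated better with another sample. Neither table holds detection calls, so no probeset was called present or absent, and low log2 values lie near the floor of the array.

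Each table holds 24128 probesets. The 112 control probesets were left out and 24016 were tested, with no filter on dim probesets and no further normalisation. A symbol was given for 17139 probesets and none for 6877, which are unnamed here. No probeset carried several symbols. Symbols were updated through the synonyms of a RefSeq gene table (assembly ARS-UCD2.0), which renamed 961 probesets and held 10320 of the 11626 distinct symbols. The files name no genome build, so no coordinates are given. Where a gene had several probesets, the brightest by mean log2 over the 6 arrays stood for it.

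Zones were compared with limma 3.58.1 in R 4.3.3. One linear model was fitted to the 6 arrays with a term for zone and a block for animal (residual degrees of freedom 2, prior degrees of freedom 4.15), and moderated tests gave SZ against MZ, SZ against DZ and MZ against DZ, with a moderated F test for any difference between the 3 zones. P-values were two-sided and adjusted over 24016 probesets by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Differences are given as log2 of the zone named first minus the other, with the model's standard error (SE), and levels as mean ± SD over the 2 animals. The block was used because arrays with the same number come from the same animal per the labels. As a check, the difference between the animals in one zone correlated with that in another with r of 0.259 for SZ and MZ, 0.216 for SZ and DZ and 0.346 for MZ and DZ across probesets, which are not independent replicates.

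Chosen before the data were examined were the design, the alternatives, 28 gene lists (8 of them markers of other cell types that a slice could hold) and the rule for naming genes. The rule took, for each comparison, up to 10 called genes with the highest and up to 10 with the lowest log2 difference among those that moved the same way in both animals, up to 4 called members of each list, and 20 fixed cartilage and bone genes. Of these 20, CILP, MATN3, SOX9 and RUNX2 had no named probeset. Genes without a descriptive symbol were skipped. Further genes were chosen for naming after their values had been seen. They were LYZ, HBB, SOX6 and CYTL1 for SZ against DZ and SLC2A3, CA9 and TOP2A for MZ against DZ. For SZ against MZ they were UST, CNMD, CD55, PDGFC, PTN, NOS2, SOD2 and COL1A2. Genes given as intermediate or lowest in MZ were also chosen in this way. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. A list was also tested with camera at an estimated correlation and with fry, and its members were adjusted over the list alone. With an estimated correlation camera uses the 2 residual degrees of freedom, so a list can hardly pass after adjustment, whatever its correlation.

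The procedure was tested on simulated data whose spread was drawn from the prior variance that limma fitted to the arrays, with genes independent of each other. Of 50 probesets shifted by log2 2, 48% were called for SZ against MZ, 60% for SZ against DZ and 52% for MZ against DZ. At a shift of log2 1 the share was 2% in each comparison, and at log2 4 it was 98%, 100% and 96%. False calls numbered 6, 4 and 8 of 24016 probesets. A shifted list was called in each comparison, and 0 of the 27 others were. As the simulated genes were independent, this does not test the list calls where genes are correlated. The estimated correlation in the real data reached 0.609, for the endothelium list.

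Alternatives were the dCHIP table, quantile normalisation, median centring, leaving out the dimmer 50% of probesets, no animal block, variance estimates with trend and robust weights, fits to 2 zones only, 1 probeset per gene, other thresholds, other list tests and leaving out each array. With 2 arrays per zone the number of arrays limits the precision, and splits of the arrays into other groups of that size were not tested. The description of both DZ arrays starts with a different code from that shared by the SZ and MZ arrays. Its meaning is not stated, and it separates DZ from the other zones completely.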

Results

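Gene expression was compared between the superficial (SZ), middle (MZ) and deep (DZ) zones of normal articular cartilage from the knees of 2 mature cattle aged between 14 and 30 months. Each zone was measured in both animals (n = 2 arrays per zone, 6 arrays in all), and the question set by the design was which genes differ between the zones. The median log2 expression was 4.42 to 4.46 on the 6 arrays, and pairs of arrays correlated with r of 0.916 to 0.972 across probesets. A limma F test found a difference between any zones for 443 of 24016 probesets. They named 286 genes. The count was 154 without DZ replicate 2, 246 without DZ replicate 1, 250 without SZ replicate 1, 271 without MZ replicate 1 and 169 without the animal block.

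The principal collagen and proteoglycan genes of cartilage were expressed near the top of the scale in every zone. COL2A1, the collagen that forms the fibril network of cartilage, was at 13.77 ± 0.12 in SZ, 14.10 ± 0.06 in MZ and 14.08 ± 0.09 in DZ (SD, n = 2). ACAN, the core protein of aggrecan, was at 12.65 ± 0.75, 13.18 ± 0.13 and 13.15 ± 0.13 in the same order, and COMP, a pentameric matrix glycoprotein, at 13.18 ± 0.39, 13.16 ± 0.47 and 13.36 ± 0.05. Neither these genes nor the small proteoglycans BGN and DCN passed the test in any comparison. As SZ minus DZ, COL2A1 differed by −0.31 (SE 0.23) and DCN by 1.01 (SE 0.37). COL2A1 read at or near the highest value of each array, which lay between 13.73 and 14.15, so a difference in it can be hidden by the end of the scale.

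**Figure D1:**
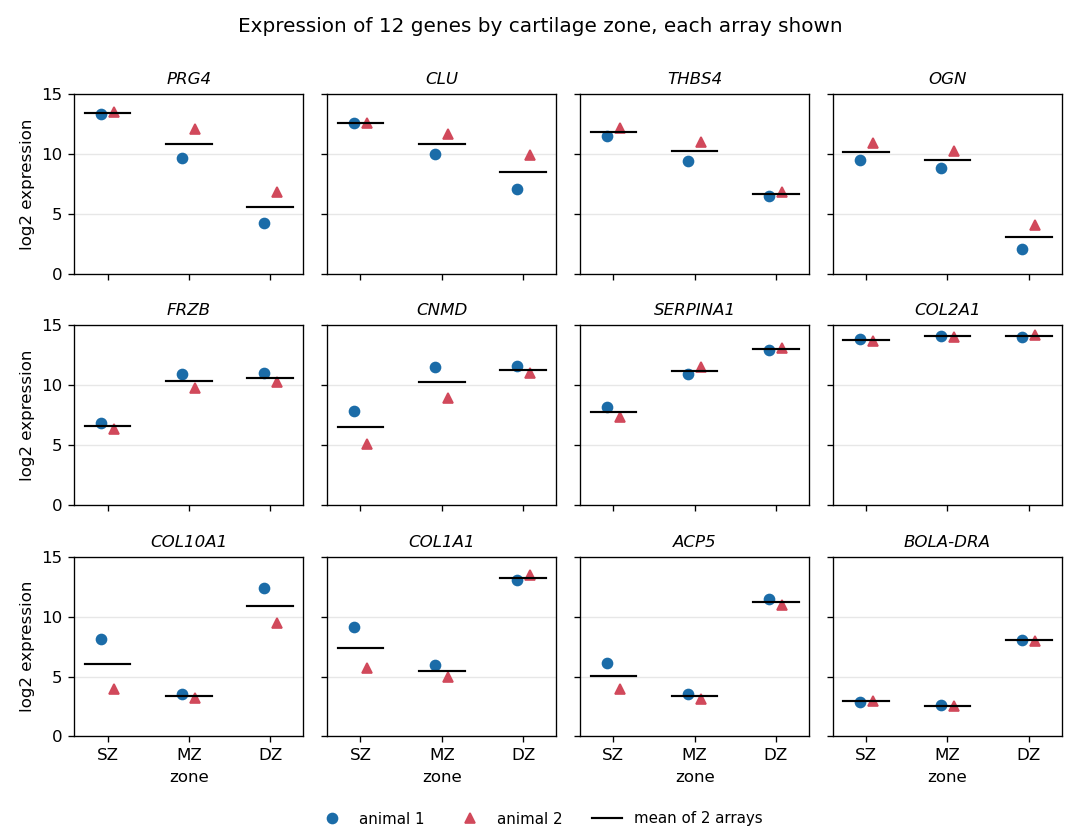
Log2 expression of 12 genes (vertical axis) in SZ, MZ and DZ (horizontal axis), with circles for animal 1, triangles for animal 2 and a line at the mean of the 2 arrays. PRG4 means run from 13.45 in SZ to 5.55 in DZ, COL2A1 means lie between 13.77 and 14.10, and COL1A1, COL10A1, ACP5 and BOLA-DRA are highest in DZ, with the 2 SZ arrays apart for COL1A1 (9.09 and 5.75) and COL10A1 (8.12 and 3.99).

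SZ against DZ gave the most called probesets of the 3 comparisons. PRG4, which encodes the joint lubricant lubricin, was higher in SZ, at 13.45 ± 0.11 against 5.55 ± 1.80 (SD, n = 2). Its SZ arrays, at 13.37 and 13.53, lie near their highest values of 13.86 and 13.73, which can understate the difference. OGN, the small leucine-rich proteoglycan osteoglycin, stood at 10.19 ± 0.97 in SZ and 3.04 ± 1.42 in DZ. In DZ, ACP5, the acid phosphatase of osteoclasts, was 71.6-fold higher than in SZ, and IBSP (bone sialoprotein) was at 10.87 ± 0.41 against 4.49 ± 1.32. DSPP, a phosphoprotein of dentin and bone, was at 9.52 ± 1.68 in DZ and 2.42 ± 0.09 in SZ. The endothelial VEGF receptor KDR was at 6.97 ± 1.23 and 1.82 ± 0.07 in the same order, and BOLA-DRA, a class II histocompatibility gene of antigen-presenting cells, at 8.01 ± 0.10 and 2.92 ± 0.05. The lower quartile of the arrays was 2.71 to 2.87 and no detection calls were used here, so folds are given only where both arrays of the lower zone read more than 1 log2 unit above it. An array of the lower zone read under its lower quartile for 10 of the 61 called genes named here for SZ against DZ (OGN, CLCA2, CXCL14, DSPP, MMP13, KDR, IGFBP3, ITGB3, PTPRC and AIF1), so the size of their differences is uncertain. Others read not far above it, such as BOLA-DRA at 2.89 and 2.95 and PECAM1 at 2.81 and 2.94 in SZ, and their sizes are uncertain too. In all, 660 of 24016 probesets passed limma's test at the adjusted threshold, 247 higher and 413 lower in SZ. They named 431 genes, 139 higher and 292 lower, and every one of the 660 moved the same way in both animals. The test was fitted to the same 2 animals and favours probesets on which they agree, so this is not a replication.

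Among the genes higher in SZ, PRG4 differed by 7.90 (SE 0.59, adjusted p = 0.00457) and OGN by 7.15 (SE 0.26, adjusted p = 0.00307). SULF2, an extracellular sulfatase of heparan sulfate, was higher by 5.99 and THBS4, the matrix protein thrombospondin 4, by 5.16. SOD3, the extracellular superoxide dismutase, was higher by 5.09 with an SE of 0.84, its DZ arrays reading 4.37 and 8.51. BMPER, a secreted BMP modulator, was higher by 5.07, the matrix protein HMCN1 by 4.81 and the metallothionein MT1A by 4.69. CLCA2 and the chemokine CXCL14 were higher by 5.14 and 5.01, and both were as low in MZ as in DZ, at 3.21 and 3.26 for CLCA2 and 2.46 and 2.36 for CXCL14. CLU, the secreted chaperone clusterin, was 17.1-fold higher in SZ (12.57 ± 0.00 against 8.47 ± 1.98, adjusted p = 0.0287). Of the 11 measured genes of the lubricating surface layer list, 3 were higher (PRG4, THBS4 and CLU) and 8 did not pass, and adjusted over the list alone 5 were higher and 0 lower. The list was higher in SZ as a whole with a median of 0.96 (camera adjusted p = 0.000165; adjusted p = 0.385 with an estimated correlation).

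Genes of hypertrophic and mineralising cartilage were lower in SZ. Of 13 measured genes of the hypertrophy and mineralisation list, 6 were lower, 0 higher and 7 did not pass, with a median of −3.30 (camera adjusted p = 2.27e-05; adjusted p = 0.385 with an estimated correlation), and adjusted over the list alone 9 were lower and 2 higher. COL10A1, the collagen of hypertrophic chondrocytes, was at 6.05 ± 2.92 in SZ and 10.91 ± 2.03 in DZ (−4.86, SE 0.82, adjusted p = 0.041). The transcription factor MEF2C differed by −3.88 (SE 0.24, adjusted p = 0.00395) and ALPL, the phosphatase of mineralising cells, by −3.81 (SE 0.41, adjusted p = 0.0115). IBSP and the collagenase gene MMP13 differed by −6.38 and −6.20. SPP1 (osteopontin) differed by −3.30 (SE 0.80) without passing (adjusted p = 0.103). Markers of bone cells were lower in SZ beside these genes. In the osteoblast list, which shares 2 of its 8 measured genes with the hypertrophy list, 3 were lower and 5 did not pass (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 7.85e-05; adjusted p = 0.385 with an estimated correlation), with the bone collagen chains COL1A1 at −5.82 and COL1A2 at −5.87. In the osteoclast list, 2 of 6 were lower, ACP5 at −6.16 and the integrin ITGB3 at −2.32, and 4 did not pass (5 lower adjusted over the list alone; camera adjusted p = 3.52e-05; adjusted p = 0.385 with an estimated correlation).

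Vessel and leukocyte markers were also lower in SZ than in DZ. Of 13 endothelial genes, 3 were lower, KDR at −5.16, the adhesion molecule PECAM1 at −3.29 (0.40 on 1 of its 2 dimmer probesets) and the angiopoietin receptor TEK at −2.71, and 10 did not pass (10 lower adjusted over the list alone; camera adjusted p = 2.2e-05; adjusted p = 0.591 with an estimated correlation). Of 15 macrophage and leukocyte genes, 5 were lower and 10 did not pass, among them BOLA-DRA at −5.09 (SE 0.23, adjusted p = 0.00347), the class II chaperone CD74 at −3.44, the pan-leukocyte phosphatase PTPRC at −2.66 (0.04 on 1 of its 3 dimmer probesets), AIF1 at −2.16 and LYZ, lysozyme, at −2.00 (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.2e-05; adjusted p = 0.385 with an estimated correlation). Red cell markers did not follow: 0 of 8 passed, with a median of 0.41 (camera adjusted p = 0.104), and HBB, a haemoglobin chain, was at 3.09 ± 0.29 in SZ and 2.59 ± 0.12 in DZ. Of 10 adipocyte markers CFD (complement factor D) was lower, at −1.47 (called in 4 of 11 alternative settings), and of 15 skeletal muscle markers 0 passed. Of 11 synovial lining and fibroblast markers, CADM1 at −3.12 and PDPN at −1.51 were lower (camera adjusted p = 0.171), each called in 4 of 11 alternative settings.

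The list of chondrocyte identity genes was lower in SZ than in DZ, but its members went both ways. SOX6 read higher in SZ, at 8.05 ± 0.21 against 7.05 ± 0.11, without passing. CYTL1 did as well, at 11.47 ± 1.15 against 10.52 ± 1.79. SOX5 and SOX9 had no named probeset. Of 9 measured identity genes 4 were lower and 5 did not pass (5 lower and 1 higher adjusted over the list alone), with a median of −1.34 (camera adjusted p = 0.00705; adjusted p = 0.385 with an estimated correlation). CNMD (chondromodulin), a cartilage inhibitor of angiogenesis, differed by −4.80 (SE 0.52), PTH1R, the receptor of parathyroid hormone-related protein, by −3.76 (SE 0.32), and the forkhead factors FOXA2 and FOXA3 by −3.48 and −2.91. The list of endoplasmic reticulum secretory genes was lower as a whole with a median of −0.35 (camera adjusted p = 0.0114; adjusted p = 0.385 with an estimated correlation), although 1 of 20 members passed, the collagen lysyl hydroxylase PLOD1 at −1.40 (2 lower adjusted over the list alone). Without SZ replicate 2 the secretory list had a camera adjusted p of 0.205 and without DZ replicate 2 one of 0.0623. PLOD1 itself was called in 3 of 11 alternative settings (highest adjusted p = 0.29), and a dimmer probeset of the gene read 0.14. CHST11, a chondroitin sulfotransferase, differed by −3.45 and COL9A2, a collagen on the surface of cartilage fibrils, by −1.74 (called in 4 of 11 alternative settings). Their lists did not pass (camera adjusted p = 0.391 for sulphation genes, 2 of 15 lower, and 0.328 for cartilage collagens, 1 of 12 lower). HAS3, a hyaluronan synthase, differed by −1.43 (adjusted p = 0.0413), but by 0.14 in the dCHIP table, and was called in 2 of 11 alternative settings.

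Secreted regulators went both ways. Of 17 WNT pathway genes 2 were higher and 1 lower (4 and 4 adjusted over the list alone), of 22 growth factor genes 3 were higher and 2 lower (6 and 2), and of 26 proteases and inhibitors 2 were higher and 2 lower (5 and 5). The WNT antagonist FRZB differed by −4.02 (SE 0.26, adjusted p = 0.00395), while SFRP1, an antagonist of the same class, was higher in SZ by 2.69 and AXIN2, a WNT target gene, by 2.59. The growth factor PTN was higher by 2.54 and IGFBP6 by 2.28, whereas IGFBP3 differed by −2.33 and MDK, a homologue of PTN, by −1.62 (called in 4 of 11 alternative settings). Among proteases and their inhibitors, TIMP2 and MMP16 were higher by 1.89 and 1.82, and SERPINA1 (alpha-1 antitrypsin) and ADAMTS6 differed by −5.24 and −2.06. The matrix proteins EFEMP1 (fibulin 3) and TNC (tenascin C) were higher by 3.07 and 2.54, and MFAP4, a microfibril-associated protein, differed by −3.12. COL15A1 was higher by 2.91, and the small proteoglycans LUM and CHAD differed by −3.20 and −1.93. SOD2, the mitochondrial superoxide dismutase, was higher by 2.33, and the stress-response genes GADD45B and KLF6 and the actin cross-linker ACTN1 differed by −2.43, −2.20 and −1.69, the call of ACTN1 being kept in 2 of 11 alternative settings (highest adjusted p = 0.186). A2M (alpha-2-macroglobulin), a broad protease inhibitor, differed by −5.35. The remaining 20 of 28 lists did not pass for SZ against DZ (camera adjusted p from 0.0534 to 0.691), and with an estimated correlation 0 of 28 did. With fry 4 lists were lower: leukocyte (adjusted p = 0.0178), chondrocyte identity (0.0271), osteoclast (0.0435) and sulphation genes (0.0435). Camera at the preset correlation had not called the sulphation list. Without the dimmer probesets 4 of the 8 called lists kept their call. Median, mean and test differed in sign for the fibrous collagens (0.44, −0.62, higher), the WNT pathway (0.35, −0.07, higher), the inflammatory response (−0.06, 0.16, higher) and adipocyte markers (0.15, −0.21, higher).

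The count of 660 for SZ against DZ became 204 without DZ replicate 2, 248 without SZ replicate 1, 337 without DZ replicate 1, 295 without the animal block and 1262 in the dCHIP table. The DZ arrays also differ from the SZ arrays in the code of their description and in 24 control probesets for Bacillus transcripts, which read 2.4 lower in log2 in DZ by the median. Whether these transcripts were added in equal amounts is not stated in the sources used here. The cyclophilin 3' minus 5' value, a measure of RNA or amplification length bias, was higher in DZ than in SZ in both animals (3.3 and 2.54 against 2.24 and 1.69).

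In MZ against DZ, COL1A1 was higher in DZ, at 13.24 ± 0.27 against 5.47 ± 0.73. ACP5 was at 11.21 ± 0.32 in DZ and 3.36 ± 0.29 in MZ and COL10A1 at 10.91 ± 2.03 and 3.38 ± 0.19. COL1A2 was at 12.28 ± 0.69 in DZ and 2.70 ± 0.35 in MZ and MMP13 at 9.50 ± 0.54 and 2.21 ± 0.04 (SD, n = 2). PRG4 was 40-fold higher in MZ. For 13 of the 32 called genes named here (OGN, GFAP, COL1A2, MMP13, DSPP, A2M, BOLA-DRA, PLS1, KDR, IGFBP3, ITGB3, PTPRC and AIF1) an array of the lower zone read under its lower quartile, so the size of their differences is uncertain. Of 24016 probesets 169 passed, 22 higher and 147 lower in MZ, naming 118 genes (12 higher and 106 lower). All 169 moved the same way in both animals, which the test on these animals favours and which is not a replication.

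The genes higher in MZ than in DZ included OGN at 6.48 (SE 0.26, adjusted p = 0.00295), PRG4 at 5.32 (SE 0.59, adjusted p = 0.028), THBS4 at 3.54 and SULF2 at 3.09. PTHLH, which encodes parathyroid hormone-related protein, was higher by 2.95 (SE 0.33, adjusted p = 0.0281), while its receptor PTH1R was lower, at −2.65 (SE 0.32, adjusted p = 0.034). GFAP, an intermediate filament gene, was higher by 3.41, TNC by 2.73, the cell-surface receptor BOC by 2.55 and LRIG3 by 1.59. The call was kept in 5 of 11 alternative settings for GFAP and in 4 of 11 for LRIG3. Of the lubricating surface layer list 2 of 11 were higher and 9 did not pass (3 higher and 2 lower adjusted over the list alone), and the list was higher (median 0.24, camera adjusted p = 0.0215; adjusted p = 0.457 with an estimated correlation). The elastic fibre and tenascin list was higher with a median of 0.52 (camera adjusted p = 0.000963; adjusted p = 0.457 with an estimated correlation), 1 of its 16 members, TNC, being called. Hypoxia and glycolysis genes were higher as a list (median 0.28, camera adjusted p = 0.00368; adjusted p = 0.457 with an estimated correlation) with 0 of 22 members past the threshold. The glucose transporter SLC2A3 read 2.69 (adjusted p = 0.0777) and CA9 1.83 (adjusted p = 0.211). Ribosomal protein genes (median 0.21, camera adjusted p = 0.0222; adjusted p = 0.603 with an estimated correlation) and skeletal muscle markers (median 0.27, camera adjusted p = 0.0326; adjusted p = 0.457 with an estimated correlation) were higher too, with 0 of 27 and 0 of 15 members called. Without DZ replicate 1 the camera adjusted p was 0.0722 for the surface layer, 0.0672 for elastic fibres, 0.0802 for hypoxia, 0.879 for ribosomal proteins (median 0.05) and 0.0585 for muscle. Without MZ replicate 1 it was 0.137 for ribosomal proteins and 0.345 for muscle. Without MZ replicate 2 it was 0.0992 for the surface layer and 0.0502 for ribosomal proteins, and without DZ replicate 2 it was 0.169 for muscle.

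Genes of mineralised tissue were lower in MZ than in DZ. In the hypertrophy and mineralisation list 4 of 13 were lower and 9 did not pass (9 lower and 1 higher adjusted over the list alone), with a median of −2.99 (camera adjusted p = 9.04e-10; adjusted p = 0.395 with an estimated correlation). COL10A1 differed by −7.53 (SE 0.82, adjusted p = 0.026), MMP13 by −7.29 (SE 0.46, adjusted p = 0.00527), ALPL by −4.60 and MEF2C by −1.92, and DSPP, outside the list, by −7.03. IBSP differed by −5.23 without passing (SE 1.03, adjusted p = 0.14), its MZ arrays reading 4.16 and 7.13. Bone cell markers were lower alongside. In the osteoblast list COL1A2 at −9.58 and COL1A1 at −7.77 were 2 of 8 that were lower (5 lower adjusted over the list alone; camera adjusted p = 6.38e-06; adjusted p = 0.395 with an estimated correlation). In the osteoclast list ACP5 at −7.85 and ITGB3 at −2.34 were 2 of 6 (4 lower adjusted over the list alone; camera adjusted p = 1.93e-06; adjusted p = 0.395 with an estimated correlation).

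Vessel and leukocyte markers were lower in MZ than in DZ as well. Of 13 endothelial genes KDR at −4.89 and TEK at −3.02 were lower and 11 did not pass (11 lower adjusted over the list alone; camera adjusted p = 2.01e-11; adjusted p = 0.457 with an estimated correlation). Of 15 leukocyte genes 4 were lower, BOLA-DRA at −5.44 (SE 0.23, adjusted p = 0.00295), CD74 at −3.97, PTPRC at −2.75 (0.09 on 1 of its 3 dimmer probesets) and AIF1 at −2.46, and 11 did not pass (9 lower adjusted over the list alone; camera adjusted p = 2.71e-10; adjusted p = 0.395 with an estimated correlation). The synovial lining and fibroblast list was lower with 0 of 11 members called (median −1.04, camera adjusted p = 0.00368; adjusted p = 0.43 with an estimated correlation). Red cell markers did not pass (0 of 8, median 0.18, camera adjusted p = 0.409), and CFD, at −1.78, was the 1 adipocyte marker of 10 that was lower (called in 4 of 11 alternative settings). A2M differed by −5.53, PLS1, an actin-bundling protein, by −5.27, the small proteoglycan LUM by −4.09, KLF6 by −2.77, the BMP pseudoreceptor BAMBI by −2.48 and IGFBP3 by −1.97 (called in 5 of 11 alternative settings).

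Further lists were lower in MZ than in DZ by smaller amounts. Chondrocyte identity genes had a median of −0.75 (camera adjusted p = 0.0456; adjusted p = 0.457 with an estimated correlation), with PTH1R as the 1 member of 9 called. Matrix proteases and their inhibitors had a median of −0.40 (camera adjusted p = 0.00368; adjusted p = 0.457 with an estimated correlation) with 0 of 26 called, and cell cycle genes one of −0.33 (camera adjusted p = 0.00368; adjusted p = 0.545 with an estimated correlation) with 0 of 21 called, TOP2A reading −1.94 (adjusted p = 0.141). Immediate-early and stress genes had a median of −0.39 (camera adjusted p = 0.0222; adjusted p = 0.457 with an estimated correlation) and mitochondrial respiratory genes one of −0.24 (camera adjusted p = 0.0265; adjusted p = 0.457 with an estimated correlation). The secretory list, with a median of −0.20 (camera adjusted p = 0.0326; adjusted p = 0.457 with an estimated correlation), and the actin cytoskeleton list (camera adjusted p = 0.0366; adjusted p = 0.457 with an estimated correlation) had 0 of 20 and 0 of 22 members called. These 7 lists lost their call without 1 array. Without MZ replicate 1 the cell cycle median was −0.03 (camera adjusted p = 0.913, the test pointing the other way) and that of immediate-early genes −0.15 (0.34). Without DZ replicate 1 they were −0.03 (0.879) and −0.02 (0.641, the test pointing the other way). Without MZ replicate 1 the camera adjusted p was 0.115 for identity genes, 0.263 for proteases, 0.344 for mitochondrial genes, 0.34 for the secretory list and 0.437 for the actin list. Without DZ replicate 1 it was 0.0585, 0.0585, 0.498, 0.0585 and 0.0802 in the same order. Without DZ replicate 2 it was 0.17 for identity genes, 0.217 for the secretory list and 0.169 for the actin list. Without MZ replicate 2 it was 0.0992 for identity genes and 0.0502 for mitochondrial genes. The 10 lists that did not pass had camera adjusted p from 0.061 to 0.768, and median, mean and test differed in sign for sulphation genes (−0.05, 0.03, higher) and adipocyte markers (0.06, −0.44, lower).

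The count of 169 for MZ against DZ became 12 without MZ replicate 2, 46 without MZ replicate 1, 74 without DZ replicate 2, 258 without either SZ array, 62 without the animal block and 259 in the dCHIP table, and the 18 called lists became 6 without DZ replicate 1, 9 without MZ replicate 1 and 0 with an estimated correlation. DZ differs from MZ in the code of its arrays' descriptions as well, and the Bacillus control probesets read 0.94 lower in DZ than in MZ by the median.

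SZ against MZ, whose arrays share a description code, gave 10 called probesets, 6 higher and 4 lower in SZ, and named 5 genes. SPON1, which encodes the matrix protein spondin 1, was higher in SZ, at 8.86 ± 0.01 against 3.17 ± 0.38 (SD, n = 2; difference 5.69, SE 0.25, adjusted p = 0.00825), and a further probeset of the gene was higher by 3.30 (adjusted p = 0.035). FRZB was 13.1-fold lower in SZ (6.61 ± 0.31 against 10.32 ± 0.82, adjusted p = 0.0339) and stood at 10.63 ± 0.49 in DZ. DPYSL3, a cytoskeletal regulator, was higher in SZ than in MZ by 3.25 (adjusted p = 0.0339), with DZ at the level of SZ (6.42 ± 0.39 against 6.65 ± 0.48), and AKR1C4, an aldo-keto reductase, by 2.65 (adjusted p = 0.0484, called in 3 of 11 alternative settings). The MZ arrays read 2.90 and 3.44 for SPON1, 2.95 and 3.87 for DPYSL3 and 3.31 and 3.27 for AKR1C4, not far above the lower quartiles of 2.8 and 2.77, so the size of these differences is uncertain. UST, a uronyl sulfotransferase of chondroitin and dermatan sulfate, was higher by 2.75 (adjusted p = 0.0414) on the dimmer of its probesets. Its MZ arrays read 2.78 and 2.85 there, near the lower quartiles, so the size of this difference is uncertain too. The brighter UST probeset read 6.40 and 5.80 in SZ and 4.63 and 3.61 in MZ and was not called. The other 4 called probesets are unnamed here and include differences of 4.60 and −4.81. An unadjusted p under 0.05 was reached by 2123 probesets, where chance alone would give 1201.

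PRG4 and CLU, called between SZ and DZ, missed the threshold between SZ and MZ. PRG4 differed by 2.58 (SE 0.59, adjusted p = 0.245), its MZ arrays reading 9.63 and 12.11, and CLU by 1.70 (SE 0.61, adjusted p = 0.486). CNMD read −3.74 (adjusted p = 0.0843), COL1A1 1.95 (adjusted p = 0.556) and COL10A1 2.67 (adjusted p = 0.393), with both collagen genes higher in the SZ array of animal 1 than in that of animal 2. By lists, 5 of 28 passed. The lubricating surface layer was higher in SZ (median 0.73, camera adjusted p = 0.000922; adjusted p = 0.573 with an estimated correlation) with 0 of 11 members called and 3 higher when adjusted over the list alone, CD55 reading 3.44 (adjusted p = 0.0627). FGF, IGF and growth factor genes were higher (median 0.31, camera adjusted p = 0.000163; adjusted p = 0.573 with an estimated correlation), with 0 of 22 called and 6 higher adjusted over the list alone, PDGFC reading 2.78 and PTN 2.43. Inflammatory and NF-kB genes were higher (median 0.31, camera adjusted p = 0.00835; adjusted p = 0.573 with an estimated correlation), with 0 of 24 called and 2 higher adjusted over the list alone, NOS2 reading 3.21 and SOD2 2.44. Fibrous collagens were higher (median 0.65, camera adjusted p = 0.0179; adjusted p = 0.573 with an estimated correlation), with 0 of 10 called and 1 higher adjusted over the list alone, COL1A2 reading 3.71 (adjusted p = 0.171) and 7.64 and 5.19 on the SZ arrays. Chondrocyte identity genes were lower (median −0.98, camera adjusted p = 0.00241; adjusted p = 0.573 with an estimated correlation), with 0 of 9 called and 4 lower adjusted over the list alone. The inflammatory list had a camera adjusted p of 0.11 without SZ replicate 2 and 0.0508 without MZ replicate 2. The fibrous collagens had 0.0599 without SZ replicate 1 and 0.129 without MZ replicate 1.

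Markers of other cells did not separate SZ from MZ: the 8 lists had camera adjusted p from 0.204 to 0.942, with 0 members called, and the sign of median, mean and test differed for osteoblast (−0.17, 0.47, higher), osteoclast (−0.05, 0.12, higher) and synovial markers (−0.11, 0.18, higher). The count of 10 probesets became 0 without either SZ array or either MZ array, 31 without either DZ array, 3 without the animal block and 135 in the dCHIP table, where 8 of the 10 were called. The Bacillus control probesets read 1.29 higher in SZ than in MZ by the median.

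**Figure D2:**
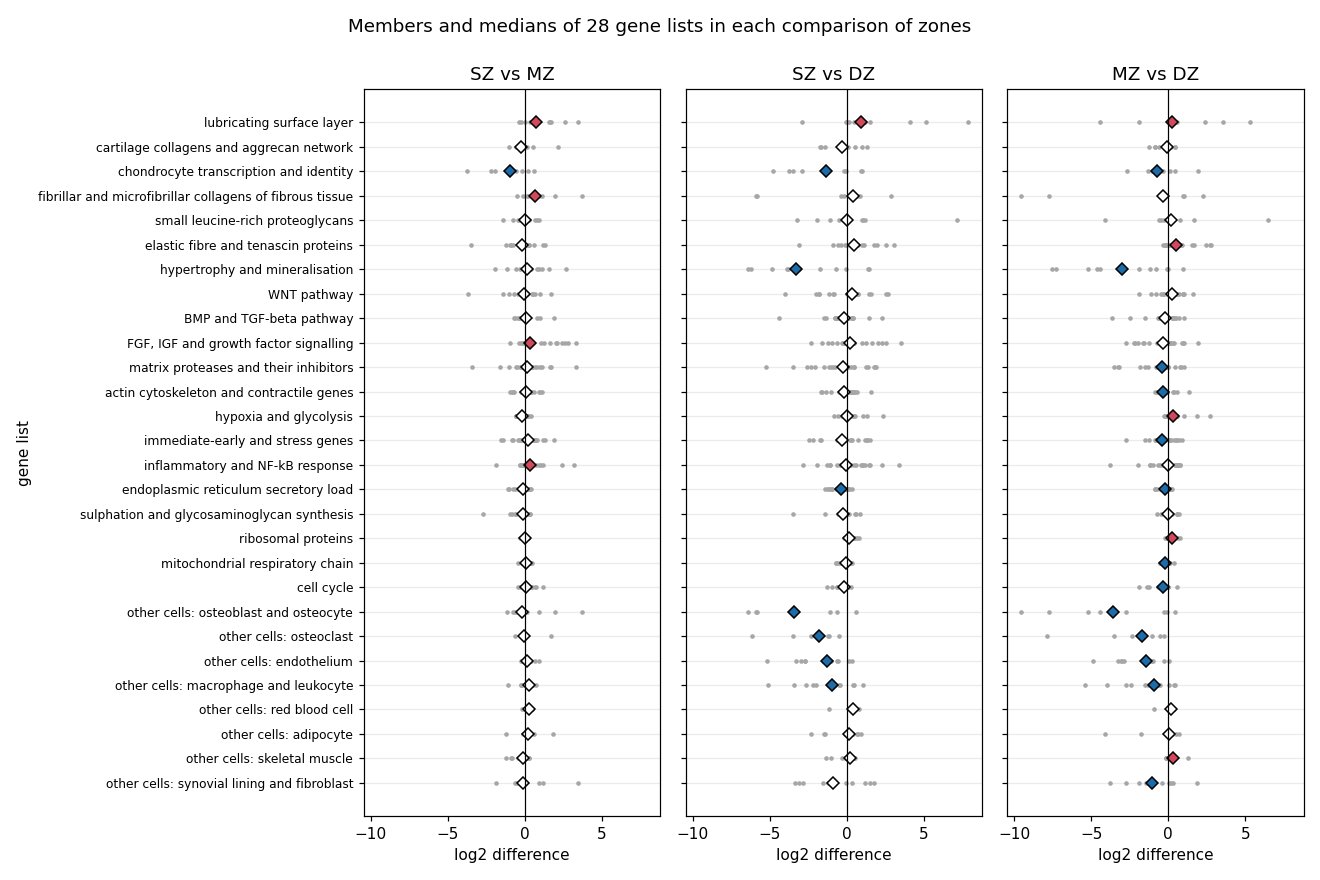
Log2 difference (horizontal axis, zone named first minus the other) for the measured members of 28 gene lists (vertical axis) in 3 comparisons, with a dot per gene and a diamond at the list's median, red where the list was higher past the threshold of camera's preset test, blue where lower and white where not past it. The hypertrophy, osteoblast, osteoclast, endothelium and leukocyte lists have medians below 0 past the threshold against DZ, with hypertrophy medians of −3.30 for SZ and −2.99 for MZ. Between SZ and MZ they did not pass, with a hypertrophy median of 0.14.

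The MZ mean lay between those of SZ and DZ for 213 of the 247 probesets higher in SZ and 317 of the 413 lower in SZ. Choosing probesets for a wide gap favours such counts, and no value for unchanged zones was computed for them. Genes with an MZ mean in between included PRG4, CLU, THBS4, MT1A, SERPINA1, at 7.78 ± 0.58, 11.21 ± 0.41 and 13.02 ± 0.13 from SZ to DZ, and MEF2C, at 6.13 ± 0.16, 8.09 ± 0.30 and 10.01 ± 0.00 (SD, n = 2). ACP5, COL1A1 and COL10A1 were lowest by mean in MZ. Of the 22 probesets higher in MZ than in DZ, 20 were also higher in SZ than in DZ, and of the 147 lower, 128 were also lower in SZ. Independent lists would share 0.226 and 2.53. In 50 simulations of unchanged zones, both compared with the same 2 simulated DZ arrays, the means were 10.7 and 55.1 and the highest values 15 and 68. The simulations include the sharing of DZ but no correlation between probesets, so part of the excess may still come from the shared arrays. Across probesets, SZ minus DZ in one animal correlated with MZ minus DZ in the other with r of 0.47 and 0.384, and probesets are not independent replicates.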

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

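The control probesets, the test of the array code and its random sets were looked at only after the results had been seen. Outside the genes compared, 24 probesets for Bacillus transcripts, which the array carries as controls, gave a signal that differed between the zones. They read 2.4 higher in log2 in SZ than in DZ by the median, with 24 of 24 higher in both animals. From SZ to MZ to DZ, their median was 6.23 and 6.44, then 5.03 and 4.59, then 3.9 and 3.68 on the arrays of the 2 animals. No control samples exist here to set these values against, and whether the transcripts were added to each RNA in equal amounts is not stated, so what the difference reflects is unknown. The hybridisation control bioB read 6.87 on DZ replicate 1 and 9.45 to 10.8 on the other 5 arrays, and the cyclophilin 3' minus 5' probesets, a measure of RNA or amplification length bias, read 2.24 and 1.69 in SZ, 2.23 and 2.66 in MZ and 3.3 and 2.54 in DZ, and those of eif4e 2.67 and 2.08, 2.5 and 3.02 and 2.67 and 2.9 in the same order. From SZ to DZ the cyclophilin value was higher in both animals and that of eif4e in animal 2, and what RNA length adds to the difference between these zones was not tested.

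A pattern that bears on each comparison with DZ is that both DZ arrays carry a different description code from the other 4, so that an effect of the array series is a candidate explanation. As the whole cause of the difference between SZ and DZ it was tested within the shared series: 500 probesets higher and 500 lower in SZ than in DZ were chosen in 1 animal, and their SZ minus MZ difference was measured in the other. The medians of both sets lay 0.694 and 1.35 apart in log2, against at most 0.121 and 0.104 for 1000 random sets, which argues against the series as the whole cause. The random sets came from all probesets and were not matched to the chosen ones in spread, so they may understate chance. The Bacillus controls also read 1.29 higher in SZ than in MZ by the median, so the shared direction need not come from the zones. For MZ against DZ the series and the zone cannot be told apart, since 0 DZ arrays share the code of the other zones. A biological difference between the zones stays open and was not separated from the series.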

How the results depend on the processing

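All alternatives here were planned before the data were examined. Over the settings run, 0 called probesets were called with the opposite sign. Of the 660 for SZ against DZ, 655 kept their sign in the dCHIP table, whether called there or not. In the other settings and pairs all that were tested kept it. A sign could turn only where a setting changed the values or left out an array of a compared zone. The rest leave each difference as it was. Quantile normalisation (8, 654, 156 and 412 probesets for SZ against MZ, SZ against DZ, MZ against DZ and any zone) and centring on medians (9, 631, 157 and 407) kept the counts within 1.5 times of 10, 660, 169 and 443. Adding a 2-fold minimum could change none of the 3 pairwise counts, as the smallest called differences were 2.65, 1.22 and 1.59 in log2. In the same order the dCHIP table gave 135, 1262, 259 and 828 probesets, and the fit without the animal block, which ignores the pairing, gave 3, 295, 62 and 169. An adjusted p under 0.1 gave 122, 1314, 282 and 808. For the 3 pairs, an unadjusted p under 0.05 with a 2-fold minimum gave 950, 2155 and 1120. For SZ against MZ, leaving out the dimmer probesets gave 180, a variance with trend and robust weights 100, 1 probeset per gene 41 and a fit to only those zones 31. For MZ against DZ, trend and robust weights gave 272 and a fit to only those zones 258, and without the dimmer probesets the share higher in MZ went from 13% to 32%. The causes were not tested, except that looser thresholds admit more calls by construction. Fewer tests need not do so: 1 probeset per gene gave 453 for SZ against DZ, 151 for MZ against DZ and 319 for any zone, fewer than in the main fit.

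Leaving out each array, with the lone array of a zone assumed to vary like the others, gave 0 to 31 probesets for SZ against MZ (0 without any SZ or MZ array, 31 without either DZ array). It gave 204 to 646 for SZ against DZ (204 without DZ replicate 2, 248 without SZ replicate 1, 337 without DZ replicate 1). For MZ against DZ it gave 12 to 258 (12 without MZ replicate 2, 46 without MZ replicate 1, 74 without DZ replicate 2, 258 without either SZ array), and for any zone 154 to 434 (154 without DZ replicate 2, 246 without DZ replicate 1, 250 without SZ replicate 1, 271 without MZ replicate 1).

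Lists past the threshold numbered 5, 8 and 18 for SZ against MZ, SZ against DZ and MZ against DZ. With an estimated correlation they were 0, 0 and 0 and with fry 0, 4 and 1. The former cannot show that correlation ends the calls, as that test has 2 residual degrees of freedom. The leukocyte list for MZ against DZ, at an estimated correlation of −0.025, went from a camera adjusted p of 2.71e-10 to 0.395. It was the 1 list called by fry there (adjusted p = 0.0144). Without the dimmer probesets the lists past the threshold were 5, 8 and 10, of which 5, 4 and 9 were among those called in the main test. In the dCHIP table they were 4, 8 and 14, of which 4, 8 and 13 were. Without each array they were 5 to 7, 8 to 11 and 6 to 19 (6 without DZ replicate 1, 9 without MZ replicate 1), and without the animal block 5, 8 and 18. The test of the cell cycle list for MZ against DZ turned its sign without MZ replicate 1, its median moving between −0.599 and −0.0306 over the arrays left out, and that of the immediate-early list without DZ replicate 1, its median moving between −0.776 and −0.0162. HAS3 for SZ against DZ turned from −1.43 to 0.14 in the dCHIP table (adjusted p = 0.796, with 0.0284 to 0.796 over all settings), the cause not tested. No other named gene that was called turned its sign.

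Of the named genes that were called, 4 for SZ against MZ, 61 for SZ against DZ and 32 for MZ against DZ, the dCHIP table kept 4, 59 and 30 and the fit without the block 1, 32 and 14. For SZ against MZ, 0 of 4 were kept without any SZ or MZ array. For SZ against DZ, 28 were kept without DZ replicate 2, 33 without DZ replicate 1 and 37 without SZ replicate 1, and for MZ against DZ, 7 without MZ replicate 2, 12 without DZ replicate 2, 14 without MZ replicate 1 and 16 without DZ replicate 1. A filter on Present calls was not run, since neither table used here holds them. With no measure of signal over background, differences between low log2 values are the least certain.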

Other observations

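All tests and genes given here were chosen after the values had been seen. In limma's F test, adjusted over all 24016 probesets, 250 genes had a difference between zones on their brightest probeset. Of these, 10 had both MZ arrays at least 1 log2 unit below every SZ and DZ array, and 0 had both MZ arrays that far above. No chance value applies to the 10, which were chosen for a zone difference and a gap. Without either choice both MZ arrays were lowest in 4.93% of 11626 genes, where chance gives 6.67%, and among the 250 in 42 (16.8%), which were chosen for a zone difference. The 10 genes included CD44, the hyaluronan receptor, the complement regulator CD55, COL1A2, DPYSL3, the interferon-induced IFITM1, the unconventional myosin MYO10, the receptor phosphatase PTPRG, TGM2 (transglutaminase 2) and THBD (thrombomodulin). TGM2 stood at 8.12 ± 1.99 in SZ, 2.41 ± 0.35 in MZ and 6.39 ± 0.59 in DZ, CD44 at 4.11 ± 0.34, 2.38 ± 0.19 and 6.72 ± 0.15 and THBD at 5.12 ± 0.06, 2.50 ± 0.10 and 4.73 ± 0.47 (SD, n = 2), with the MZ levels near the arrays' lower quartile. In the pairwise tests 1 of the 10, DPYSL3, passed against both SZ (adjusted p = 0.0339) and DZ (0.00906). Another 6 passed against DZ alone, among them CD44 (0.0759 against SZ and 0.00499 against DZ) and THBD (0.0568 and 0.0402), and 3 passed against neither: CD55 (0.0627 and 0.174), MYO10 (0.0767 and 0.0741) and TGM2 (0.0631 and 0.103).

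Single genes higher in SZ than in DZ included MT2A, a metallothionein, by 2.49. Single genes lower in SZ than in DZ included CLEC14A at −3.06 and ECSCR at −2.92 (1 probeset per gene), whose SZ levels of 3.14 to 3.32 lie near the arrays' lower quartile.

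Between the animals 11 probesets passed limma's test, 9 higher and 2 lower in animal 2, against 2904 at an unadjusted p under 0.05. 6 of them belong to XIST, higher by up to 8.35 in animal 2, and ZFY differed by −3.20. The XIST means were 2.25 to 3.03 in animal 1 and 8.23 to 11.38 in animal 2, and those of ZFY 4.68 and 1.48. With XIST a transcript of female cells and ZFY a gene of the Y chromosome, this is the pattern of a male animal 1 and a female animal 2. The animal block therefore cannot be told apart from sex. BOLA-N, a class I histocompatibility gene, was higher by 4.72, XDH (xanthine dehydrogenase) by 2.79 and GPLD1 by 2.54. The immediate-early gene EGR1 read 11.27 and 11.25 in SZ and MZ of animal 2 but 7.27 and 5.97 in animal 1, with 8.01 and 8.13 in DZ of animals 1 and 2. NR4A2 read 10.66 and 8.73 in SZ and MZ of animal 2 and 5.93 and 5.66 in animal 1. The proteoglycan VCAN read 10.2 in SZ of animal 1 and 6.04 to 7.26 on the other arrays, and DPT (dermatopontin) read 8.11 in SZ of animal 1 and 3.62 in SZ of animal 2.

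Bone, vessel and leukocyte markers were higher in DZ together, and a hypothesis is that the DZ slices held bone and marrow cells. Of 42 markers of their 4 lists, 34 (81%) had both DZ arrays above all 4 others, against 6.67% by chance and 10.3% of all genes. The share was 87.5% for osteoblast, 83.3% for osteoclast, 76.9% for endothelial and 80% for leukocyte markers. These 4 were picked from the 8 lists of other cells after the list tests had been seen. Their shares count again what those tests had shown and so do not bear on where the transcripts came from. The remaining lists gave 54.5% for synovial lining and fibroblast, 20% for adipocyte and 0% for red cell and for muscle markers. COL1A1, COL1A2 and ACP5 reached 13.24, 12.28 and 11.21 in DZ, while SPARC, which cartilage also expresses, read 12.9 in SZ and 13.5 in DZ, and the labels give sectioning only down to the calcified cartilage. The most abundant transcripts of blood stayed low in DZ, with HBA at 4.14 and 3.50 and HBB at 2.68 and 2.51 (−0.267 relative to the other zones). BOLA-DRA reached 8.01 there. Of 8 red cell genes 0 had both DZ arrays above the rest, although EPB42 read 4.16 in DZ replicate 1 (1.02 for DZ relative to the other zones). These values argue against blood only if the probesets respond to it. HBB read 2.51 to 3.30 over the 6 arrays, and no array here shows such a response. The same values bear on marrow where it holds red cells. Bone and marrow cells and DZ chondrocytes cannot be told apart as sources, since no array here holds either cell type alone and the counts highest in DZ (78.6% of endothelial and leukocyte markers, 5 of 6 osteoblast markers outside the hypertrophy list) only repeat the pattern, and the array series of DZ is a further open explanation.

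Bone transcripts also stood higher in SZ replicate 1 than in SZ replicate 2, with COL1A1 at 9.09 and 5.75. If RNA of the DZ slices of the same animal had entered that SZ sample, a share of 5.8% would give the COL1A1 excess and predict a median excess of 1.43 in log2 for the 23 other genes called lower in MZ than in DZ whose predicted excess was at least 1, where 0.743 was seen (quartiles 0.274 and 1.37). COL10A1 (4.12 seen, 4.32 predicted) and COL1A2 (2.45, 2.73) lay near the prediction, while DSPP (0.129, 2.21), BOLA-DRA (−0.06, 1.6) and KDR (0.09, 1.12) lay below it. A difference between the animals would raise the same genes in the other zones of animal 1, where the median excess was 0.398 in MZ and 0.456 in DZ. Both explanations stay open, as the values fall between what each predicts and what would exclude it.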
